A study of Arabidopsis thaliana with 2 samples.

How the data were processed

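Open flowers of wild type and of an sdg4 T-DNA line of Arabidopsis thaliana were compared on 2 two-colour Agilent arrays. Per the labels, total RNA was extracted with Trizol, amplified and labelled with an Agilent linear amplification kit, with wild type in Cy3 and sdg4 in Cy5 on both arrays. The labels' titles number the arrays as replicates 1 and 2 while both descriptions say replicate 1, and the numbers of the titles were used. Both arrays lay on 1 slide and were scanned together, so no slide or scan batch could be tested.

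Per the file headers, the deposited scanner output was extracted with Agilent Feature Extraction 9.1.3.1 and holds spot intensity values on a linear scale. The mean signal and the local median background of each channel were used. Of 39102 spots per array, 1417 were controls. The software's processed intensity signals, which per the file headers were spatially detrended and dye-normalized, with lowess settings listed, served as an alternative. The deposited series table holds log10 ratios of red over green, which equalled the ratios in the scanner output within 2.2e-16 and had a median of 0 on each array. Its scale and direction are thus known, and its centring is that of the software. The genome build behind the probe names is not given in the sources used here.

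The 37685 other spots carried 37478 probes, of which 26236 named one of 25665 gene loci. Of these loci, 25449 were found in the RefSeq table of assembly TAIR10.1, which was used for symbols and for which genes are neighbours. The 11242 probes without a locus name, mostly genomic intervals and cDNA clones, were left out of the gene comparisons.

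Signals were analysed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, which shrinks ratios of dim spots, and ratios were normalized within each array by loess with control spots at weight 0. Outlier spots marked by the software, 35 on the replicate 1 array and 28 on the replicate 2 array, were left out. No spot was saturated. Spots of 1 probe were averaged, and the brightest probe stood for each of the 541 loci with several. A locus was kept where its probe was well above background in the same channel on both arrays, leaving 20267 loci. Where a probe was not well above background in the samples of 1 genotype, a lower bound of the fold is given. It sets the bright genotype's mean against the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own signal, per channel after loess and Aquantile normalization, and it is open to dye bias.

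Each gene was tested with lmFit and eBayes on the 2 log2 ratios against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each gene had 1 residual degree of freedom, and the prior added 1.90. Before the data were examined, 19 gene lists were fixed from textbook knowledge. Of their 304 entries, 3 were dropped because the reference table gives the symbol to another locus. Lists were tested with camera, two-sided, with a preset correlation of 0.01 and with an estimated one, and adjusted over the lists. With the estimated correlation the test has only the 1 residual degree of freedom, on which hardly any list can pass the adjustment. A call lost there thus tells little of the correlation itself. The preset correlation takes the genes of a list as nearly independent. The estimates were 0.83 for jasmonate, 0.84 for pollen tube signalling and 1 for pollen cell wall genes. With 1 residual degree of freedom, an estimate reflects only on which array each member's ratio was higher. It thus shows that most members moved the same way between the arrays, but not how strongly they correlate. The medians of the lists were ranked among 10000 random lists matched on mean intensity, which describes these arrays only. The named genes also followed a rule fixed before the data were examined. It takes SDG4 and 2 annotated neighbours on each side. Per direction it takes the 12 genes with the largest ratio past the threshold, filled with those of the smallest p among genes at least 2-fold apart in the same direction on both arrays. It also takes up to 4 members with the smallest p from each list called by camera and from the pollen, sperm cell and tapetum lists. Exceptions are named as such.

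The steps were tested on simulated data of 20267 genes with the variances that limma fitted to these arrays, 200 of them changed. Among the unchanged genes 3 passed the threshold, and 194 were at least 2-fold apart in the same direction on both arrays, more than the arrays themselves held, so that the simulated spread is too wide to give a chance value for that count. In simulated lists, the 1 shifted list was called and 0 of the others. These lists held independent genes, so they do not test the preset correlation on lists whose genes vary together.

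Alternatives fixed before the data were examined were no background subtraction, an offset of 16, the processed signals, the deposited log10 ratios, median centring, scaling between arrays, no filter or a stricter one, keeping outlier spots, the mean over probes, a trended robust variance, separate channels with no replicate block, a correction for probe GC content, an estimated correlation in camera, and leaving out each array. Precision is set by the number of arrays and by signal over background, whose medians were 2.71 and 4.69 on the replicate 1 array for wild type and sdg4 and 2.55 and 3.74 on the replicate 2 array.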

Results

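Transcript levels in open flowers of Arabidopsis thaliana were measured on 2 two-colour oligonucleotide arrays. On each array, RNA of flowers labelled as the sdg4 mutant, a line with a T-DNA insertion, was labelled with Cy5 and set against RNA of wild type flowers labelled with Cy3. There were 2 biological replicates of each genotype, grown and harvested separately, and each array held 1 replicate pair. SDG4 (AT4G30860) encodes a protein with a SET domain, the catalytic domain of many histone methyltransferases, and is known from its literature to act in pollen. The comparison asks which flower transcripts differ between the mutant line and the wild type. The median spot signal on the replicate 1 array was 108 in the wild type channel and 220 in the sdg4 channel, against median local backgrounds of 40 and 47. On the replicate 2 array the medians were 102 and 176, against the same median backgrounds. Between 61.9% and 67.8% of non-control spots were well above background in a channel. After filtering, 20267 gene loci were compared. With 2 arrays, the number of arrays limits the precision of every value, and because the dyes were not swapped, a probe's own dye bias cannot be told apart from a genotype difference. All ratios are log2 of sdg4 over wild type, given as mean ± SD over the 2 arrays or array by array.

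The SDG4 transcript was not lower in the samples labelled sdg4. Its single probe gave a log2 ratio of 1.66 ± 0.10 (SD, n = 2), a 3.16-fold higher signal in the samples labelled sdg4, with 1.59 on the replicate 1 array and 1.73 on the replicate 2 array. The direction goes against the label of a disrupted gene. Where the probe lies relative to the insertion was not analysed here, so the value does not settle whether the full transcript was present. An exchange of the channel labels on both arrays, which would turn every direction, was not excluded either. Directions below are given as those of the samples labelled sdg4. HHP2 (AT4G30850), the adjacent annotated gene on one side, which encodes a heptahelical membrane protein, gave 1.83 ± 0.21 (SD, n = 2), and its 2 probes gave 1.69 and 1.66 on the replicate 1 array and 1.98 and 1.99 on the replicate 2 array. Both genes differed by more than the spread between the arrays and were at least 2-fold higher on each, but neither passed the limma test over all genes (adjusted p = 0.887 for both). Of the remaining annotated neighbours within 2 genes on each side, MUS81 (AT4G30870) had a probe that did not pass the filter on background, and AT4G30845 and AT4G30872 had no probe on the array.

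A few transcripts were far lower in the samples labelled sdg4 on both arrays. MRD1 (AT1G53480) was 65.2-fold lower, with a log2 ratio of -6.03 ± 0.26 (SD, n = 2). AT3G01345, annotated only as an expressed protein, was 20.8-fold lower, with -4.38 ± 0.25 (SD, n = 2). AT5G03090, a hypothetical protein, was not well above background in the samples labelled sdg4 and was at least 3.23-fold lower there. HIR2 (AT3G01290), of a family linked to the hypersensitive response, gave -1.04 ± 0.02, and GATL6 (AT4G02130), of glycosyltransferase family 8, gave -1.28 ± 0.25. These 5 were all the genes at least 2-fold lower on both arrays.

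At least 2-fold higher on both arrays were 25 genes, among them SDG4, HHP2 and a group of heat shock genes. The 12 with the smallest p included the small heat shock proteins AT1G59860 (HSP17.6A-CI), at 3.39 ± 0.92, and AT2G29500 (HSP17.6B-CI), at 2.38 ± 0.14 (SD, n = 2). HSP17.6A (AT5G12030) was not well above background in the wild type channel on either array. It was at least 2.44-fold higher in the samples labelled sdg4 on the mean of the 2 arrays, a bound equal to its measured mean. The single arrays gave 2.25-fold and 2.65-fold. AT3G14200, a protein with a DNAJ domain, gave 1.13 ± 0.17. The invertase or pectin methylesterase inhibitor proteins AT1G70720 and AT3G17130 gave 1.42 ± 0.19 and 1.28 ± 0.13. The remaining members of the 12 were KDR (AT1G26945), an atypical helix-loop-helix protein, at 1.16 ± 0.03, DIP2 (AT5G03210) at 1.84 ± 0.52, and AT4G27657 at 1.51 ± 0.35, and AT4G10290, a hypothetical protein, at 1.41 and 1.38.

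None of these genes passed the test over all genes. With limma, 0 genes were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.887. At an unadjusted p under 0.05 there were 457 higher and 260 lower genes, 717 in all, where chance alone gives 1013. With the channels treated as separate samples, limma called 2 genes, MRD1 (adjusted p = 0.0213) and AT3G01345 (adjusted p = 0.0373). That fit ignores the pairing of the channels on an array and takes them as independent. In data simulated from the variances that limma fitted to these arrays, which spread more widely than the arrays' own ratios, the test on ratios recovered 42 of 50 genes changed 32-fold and 19 of 50 changed 8-fold, and 0 of 50 changed 4-fold.

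After loess normalization, the profiles of the 2 arrays had little in common beyond these genes. On the replicate 1 array 547 genes were at least 2-fold higher and 473 at least 2-fold lower in the sample labelled sdg4, and on the replicate 2 array 195 and 128. The 25 genes shared in the higher direction and the 5 in the lower direction compare with 5.26 and 2.99 that independent lists of these sizes share. At least 2-fold in opposite directions were 82 genes, of which 55 were lower on the replicate 1 array and higher on the replicate 2 array, where independent lists give 8.01. Independence takes all genes to vary alike, and genes in opposite directions outnumbered those shared, so the overlap is not shown to exceed chance. Across genes, which are not independent replicates, the log2 ratios of the arrays had a Pearson correlation of -0.13 and a Spearman correlation of -0.02, and with median centring 0.14 and 0.24. The shared counts were 190 higher and 3 lower with median centring, which left the median of all genes at 0.48 and 0.42, and 78 and 23 with the software's processed signals.

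**Figure D1:**
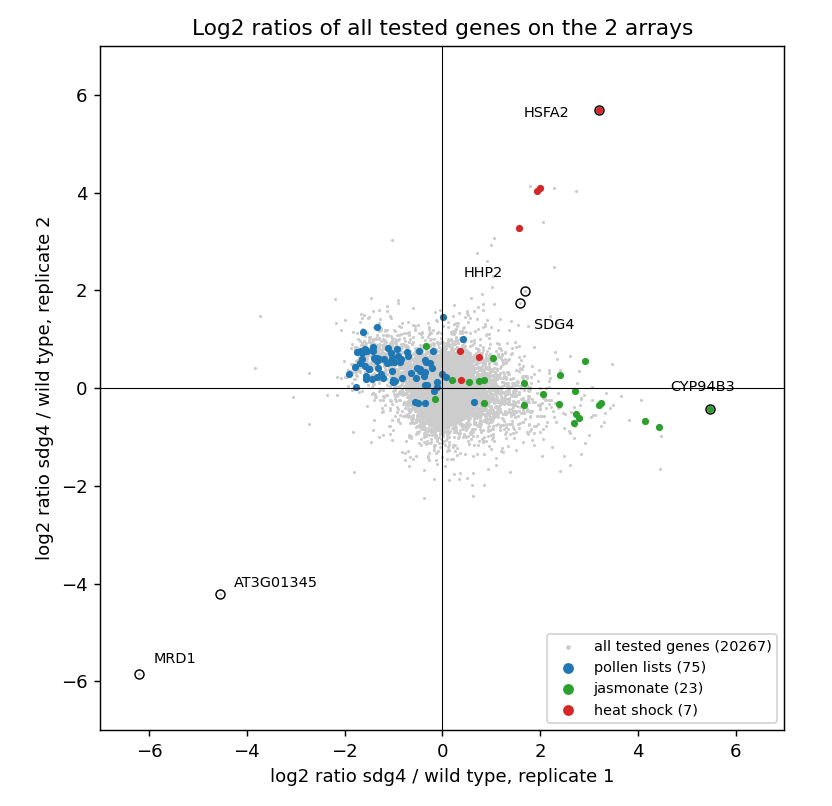
Log2 ratio of sdg4 over wild type for each of the 20267 tested genes, replicate 1 on the horizontal axis and replicate 2 on the vertical axis, with members of the pollen lists (75), the jasmonate list (23) and the heat shock list (7) in colour. MRD1 and AT3G01345 lie far below 0 on both arrays, heat shock genes above 0 on both, jasmonate genes extend to 5.48 on replicate 1 alone (CYP94B3), and most pollen genes lie below 0 on replicate 1 and above 0 on replicate 2.

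Heat shock genes were higher in the samples labelled sdg4. All 7 measured members of the 9 in the list were above 0 on both arrays, with a median log2 ratio of 1.57 on the replicate 1 array and 3.28 on the replicate 2 array. HSFA2, a transcription factor of the heat response, gave 4.45 ± 1.75 (SD, n = 2). HSP101, a chaperone that dissolves protein aggregates, gave 3.05 ± 1.49, and HSP70 gave 2.98 ± 1.47. HSP17.6II was not well above background in wild type and was at least 1.585-fold higher on the mean of the 2 arrays. The single arrays gave 1.68-fold and 1.56-fold. Of the list, 4 members were at least 2-fold higher on both arrays, 5 passed when adjusted over the list alone, and 0 passed over all genes. The list passed limma camera with a preset correlation of 0.01 (adjusted p = 4.1e-07). The call was lost with an estimated correlation of 0.048 (adjusted p = 0.95), a test on 1 residual degree of freedom that hardly any list can pass. Both medians stood at percentile 100 of 10000 random lists matched on intensity. With no filter on background, which adds HSP21 and HSP22, the medians were 0.75 and 0.76 over 9 members, and the list passed camera with the preset correlation. With median centring in place of loess the medians were 2.14 and 3.78, where those of all genes were 0.48 and 0.42. The list did not pass camera in that setting (adjusted p = 0.0839).

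Jasmonate genes were far higher on the replicate 1 array and not on the replicate 2 array. The median of the 23 measured members was 2.39 on the replicate 1 array, where 16 were at least 2-fold higher, and -0.23 on the replicate 2 array, where 0 were, at the percentiles 100 and 0.14 of random lists. With median centring in place of loess these medians were 3.09 and 0.27, where the medians of all genes were 0.48 and 0.42. The lipoxygenases LOX3 and LOX4, which start jasmonate synthesis, gave 4.16 and 4.44 on the replicate 1 array against -0.66 and -0.80 on the replicate 2 array. CYP94B3, which inactivates the hormone, gave 5.48 and -0.43, and OPR3 gave 3.22 and -0.34. These 4 were chosen after their values were seen. The 4 members with the smallest p were above 0 on both arrays, which a p on the mean of the 2 ratios favours. On the replicate 2 array 14 of the 23 members were below 0, so these 4 do not show a shared rise of the list. MYB21, a stamen transcription factor, gave 0.83 ± 0.29, AOC3, an allene oxide cyclase, 1.74 ± 1.67, and the storage proteins VSP1 and VSP2 gave 0.51 ± 0.48 and 0.45 ± 0.42. The second probe of MYB21 gave 0.79 and -0.09 on the arrays. Over both arrays the list passed camera with the preset correlation (adjusted p = 6.1e-05), a call that rests on the replicate 1 array. It was lost with an estimated correlation (adjusted p = 0.95), a test on 1 residual degree of freedom that hardly any list can pass. With median centring the list did not pass camera either (adjusted p = 0.365). No member passed over all genes, nor when adjusted over the list alone.

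Pollen genes lay on opposite sides of 0 on the 2 arrays. Over the 75 measured members of the 5 pollen lists, the median was -1.02 on the replicate 1 array, a 40-member majority being at least 2-fold lower, and 0.52 on the replicate 2 array, where 70 were above 0. The percentiles among random lists were 0 and 100. The median over the mean ratios was -0.30, with camera giving p = 0.00132 in the lower direction and p = 0.703 with an estimated correlation. Leaving out the replicate 1 array turned the direction, to 0.52, and median centring, which left the median of all genes above 0, gave 0.13, with array medians of -0.66 and 0.86. Not a single pollen gene was at least 2-fold apart in the same direction on both arrays, and 0 passed over all genes or when adjusted over a list alone.

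**Figure D2:**
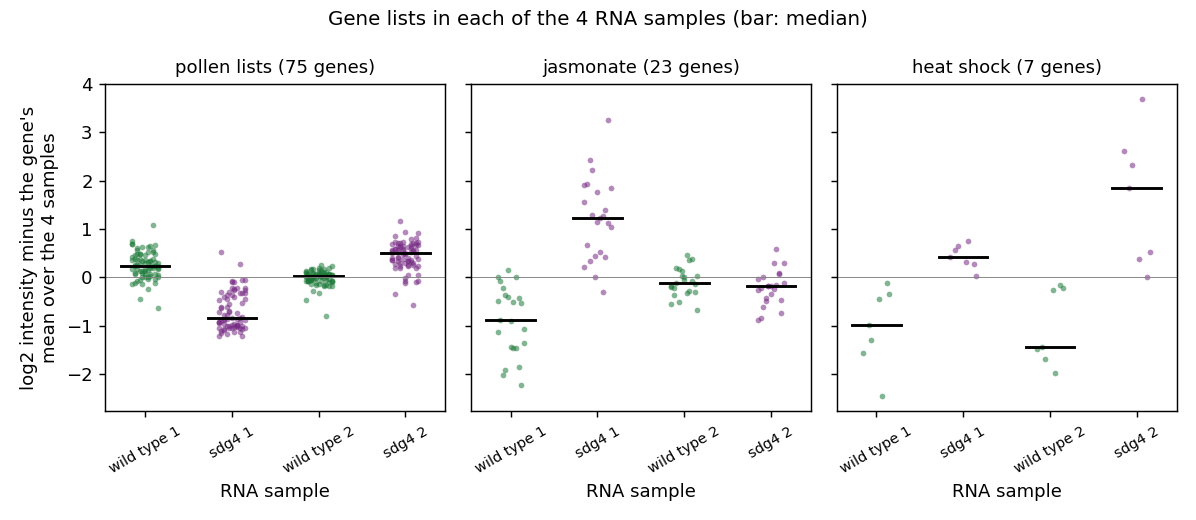
Log2 intensity of each measured member of the pollen (75 genes), jasmonate (23) and heat shock (7) lists in each of the 4 RNA samples, after loess and Aquantile normalization and minus the gene's mean over the samples, with the list median as a bar. The pollen medians are 0.24 and -0.84 in wild type and sdg4 of replicate 1 and 0.03 and 0.50 in those of replicate 2, and the jasmonate medians are -0.88, 1.23, -0.12 and -0.19 in the same order.

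Among the pollen lists, cell wall genes gave medians of -1.46 and 0.60 over 18 members. VGD1, a pectin methylesterase of pollen tubes, gave -1.79 and 0.43, CSLD1, a cellulose synthase-like protein, -1.76 and 0.01, and SKS12 -1.26 and 0.28, while PPME1, another pectin methylesterase, gave 0.42 and 1.00. Pollen tube signalling genes gave medians of -1.29 and 0.53 over 25 members. The receptor kinase BUPS1 gave -1.56 and 0.18, the calcium-dependent kinases CPK17 and CPK34 -1.55 and 0.25, and -1.44 and 0.18, and the receptor kinase PRK1 0.01 and 1.45. Smaller medians were found for cytoskeleton genes, with -0.38 and 0.22 over 13 members. The pollen actins ACT4 and ACT12 gave -1.02 and 0.12, and -1.01 and 0.17, whereas ACT11 gave -0.49 and -0.31 and the formin FH5 0.07 and 0.22. Transport genes gave medians of -0.45 and 0.29 over 11 members, and -1.18 and 0.50 with the software's processed signals, with the sugar transporters STP11 at -1.91 and 0.29 and STP10 at -0.35 and -0.31, the channel CNGC8 at -0.01 and 0.29, and the aquaporin TIP1;3 at -0.16 and -0.06. Pollen transcription factors gave -0.51 and 0.56 over 8 members, with AGL18 at -1.04 and 0.61, AGL66 at -0.55 and 0.20, AGL104 at -0.35 and 0.58, and AGL30 at -0.55 and -0.28. The camera adjusted p of these 5 lists lay between 0.0891 and 0.601, so no single list was called.

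**Figure D3:**
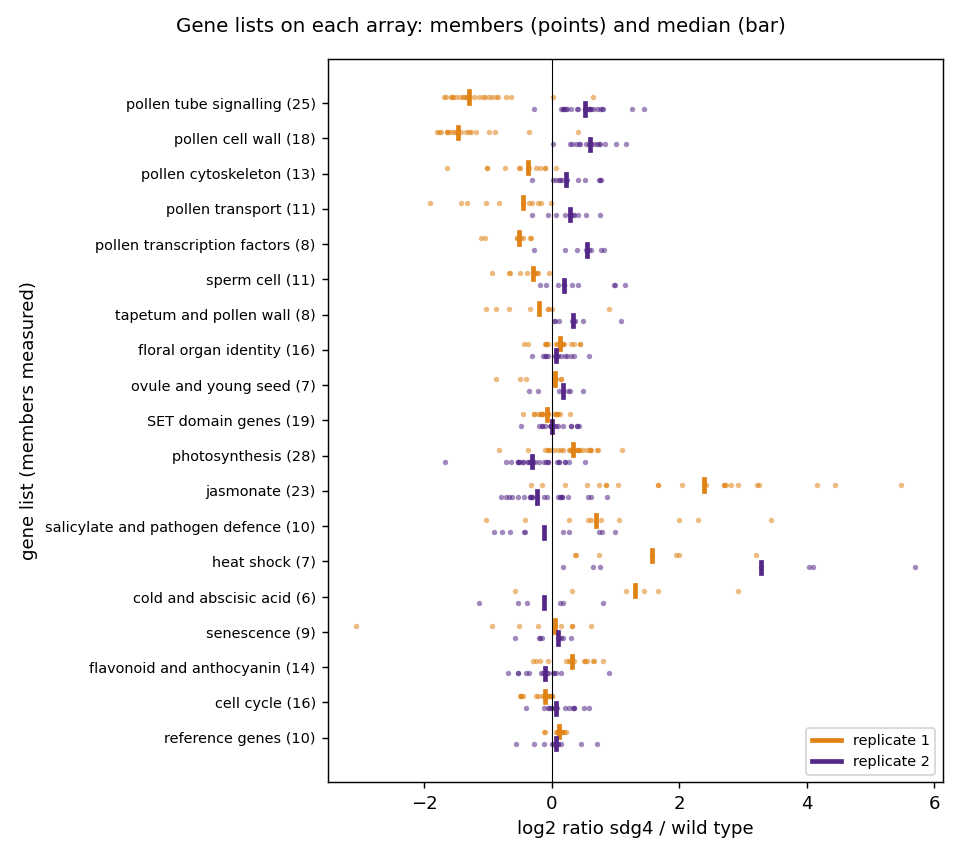
Log2 ratio of sdg4 over wild type for the measured members of each of the 19 gene lists (points) and their median (bar), for the replicate 1 and the replicate 2 array. The pollen lists have medians from -1.46 to -0.38 on replicate 1 and from 0.22 to 0.60 on replicate 2, and the heat shock list has medians of 1.57 and 3.28.

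Sperm cell genes gave medians of -0.30 and 0.19 over 11 members, with camera adjusted p = 0.601, and medians of -0.69 and 0.81 with the software's processed signals. All 11 were below 0 on the replicate 1 array and 9 were above 0 on the replicate 2 array. The percentiles among random lists were 0.04 and 97.7. The members with the smallest p, a rule that favours like ratios on both arrays, differed less. DAN1 gave -0.26 and 0.10, GEX2 -0.26 and -0.10, DUO1, the master regulator of the male germline, -0.39 and 0.19, and DAZ2 -0.04 and -0.18. GEX1 gave -0.93 and 0.98, PCR11 -0.68 and 1.15, and TIP5;1 -0.65 and 1.00, all picked after their values were seen. The probes of DUO1 and DAZ2 were well above background in wild type on 1 of the 2 arrays. Of 24 genes of the tapetum and pollen wall, 8 were measured, with medians of -0.20 and 0.33 (camera adjusted p = 0.741). CYP704B1, a fatty acid hydroxylase of sporopollenin synthesis, gave 0.99 ± 0.13 (SD, n = 2) and was the 1 member that passed when adjusted over the list alone. LAP5 gave -0.87 and 0.04, TKPR1 -0.06 and 0.36, and GRP17, a pollen coat protein well above background in wild type on 1 array, -1.03 and 0.49.

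The other lists did not pass camera. Photosynthesis genes gave opposite medians of 0.34 and -0.30 over 28 members, with percentiles of 100 and 0 among random lists, and with median centring 1.24 and 0.42. Cold and abscisic acid genes gave 1.31 and -0.13 over 6 members, and salicylate and pathogen defence genes 0.70 and -0.12 over 10. Flavonoid and anthocyanin genes gave 0.32 and -0.10 over 14 members. Floral organ identity genes gave 0.12 and 0.07 over 16, the other SET domain genes -0.07 and 0.01 over 19, and ovule and young seed genes 0.05 and 0.17 over 7. For this last list the mean of the members' mean ratios, -0.04, and the camera direction were below 0 while their median, 0.04, was above it. Senescence genes gave 0.05 and 0.11 over 9, cell cycle genes -0.11 and 0.07 over 16, and the 10 reference genes 0.12 and 0.06. The camera adjusted p of these lists lay between 0.187 and 0.862.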

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

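The patterns examined here were themselves found in the results. For other normalizations and for how far single samples stand apart, the predictions were written before those tests were run. All other tests were chosen after the results were seen.

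Signals outside the gene comparisons came from probes without a locus name and from spiked-in control RNA. Of 2984 such probes that passed the filter, 4 were at least 2-fold lower on both arrays, 0 were at least 2-fold higher, and 1 went in opposite directions. One of the 4, a genomic interval on chromosome 1 from 10776117 to 10776176 in the array's own coordinates, whose build is not given in the sources used here, had a mean log2 ratio of -3.70. It was not well above background in the samples labelled sdg4 and was at least 11.1-fold lower there. The log2 ratios of the 10 spike-in probes lay higher on the replicate 2 array by a median of 1.33 ± 0.16 (SD over probes), with a Pearson correlation of 0.997 between the arrays across probes. Their intended ratios were not used here.

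The opposite sign of pollen genes on the 2 arrays was not removed by other normalization or background settings, since all 6 kept the pollen median under -0.5 on the replicate 1 array and over 0.2 on the replicate 2 array. Less pollen in equal proportion in the sdg4 sample of replicate 1 stays open. There, 6 sperm cell genes lay 0.81 above 36 genes of the pollen tube signalling and pollen cell wall lists together. All were of mean log2 intensity over 8 (permutation p = 0.00173, two-sided, genes not being independent). With the processed signals the gap was 0.84. On the replicate 2 array both groups had like medians of 0.69 and 0.59. The comparison cannot decide, because those 2 pollen lists had the lowest medians on the replicate 1 array. The other 3 pollen lists, with medians of -0.38, -0.45 and -0.51 there over all members, were not compared. The 6 sperm cell genes had a median of -0.57 there. The gap may thus not be particular to sperm cell genes. An exchange of channels on 1 array was first tested on the 19 genes with log2 ratios of at least 1.5 in size on both arrays, of which 14 (73.7%) had the same sign, short of the 80% set to exclude it, but it is argued against by SDG4 and the adjacent HHP2, which were at least 1.59 on both arrays where an exchange would turn 1 of them, and which dye bias would have to hit together although 0.123% of tested genes were 2-fold higher on both. With that, the 93.3% of pollen genes above 0 on the replicate 2 array argue against a shared genotype effect as the whole cause. Since pollen genes vary together and each array held 1 sample pair, a smaller shared effect masked by differences between samples stays open. The sdg4 sample of replicate 1 lay 0.87 below the nearest of the other 3 samples in pollen genes, which themselves spanned 0.48, so a property of that sample, such as its handling, may underlie the larger part, untested, whereas the tapetum medians set the replicates apart (0.38 and 0.41 in wild type and sdg4 of replicate 1, -0.50 and -0.21 in those of replicate 2) and not that sample.

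Jasmonate genes were higher on the replicate 1 array, with a median over 1 in all 6 other normalization or background settings, which argues against these as the cause. With an exchange of channels on 1 array argued against as above, the median of -0.23 on the replicate 2 array argues against a genotype effect shared by both replicates as the whole cause. A smaller shared effect masked by differences between samples stays open, since each array held 1 sample pair. The sdg4 sample of replicate 1 lay 1.36 above the nearest of the other 3 samples, which spanned 0.75. Within that span the wild type sample of replicate 1 stood lowest. Its median was -0.88, against -0.12 and -0.19 in wild type and sdg4 of replicate 2. A part of the replicate 1 ratio thus lies in that wild type sample. For the rest, a candidate explanation is a wound or handling response of the sdg4 sample of replicate 1, untested. A genotype effect that shows in some plants only also stays open, untested.

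Heat shock genes kept a median over 0.5 on both arrays in all 6 other normalization or background settings. Under median centring all genes had medians of 0.48 and 0.42, so that cut-off says little there. The heat shock medians were 2.14 and 3.78 in that setting, although the list no longer passed camera (adjusted p = 0.0839). These medians argue against normalization as the cause of the higher ratios. The correction for probe GC content moved no ratio by more than 0.102 and so tests little, but the 10167 other genes with the probe GC content of the heat shock genes had medians of -0.0072 and -0.016 on the arrays, which argues against that content as the cause. Dye bias shared by both arrays would give equal ratios, and although the exact two-sided sign-flip test chosen first missed the threshold (p = 0.0625, 0.0156 being the smallest it can give), the ratios on the replicate 2 array were higher by a median of 1.71 over the 7 members, and 0 of 10000 random lists matched on intensity differed as much (largest 0.87). Random lists hold mostly genes with ratios near 0, so they do not show how far probes of large dye bias can differ between arrays. The difference argues against dye bias of equal size on both arrays as the whole cause for the list, but it rests on HSP70, HSP101, HSP90.1 and HSFA2, and dye bias stays open for HSP18.2 (0.38 and 0.17), HSP17.6II (0.75 and 0.64) and HSP17.4 (0.36 and 0.76) and for a part of each other ratio, since no array had the dyes swapped. A genotype effect and a difference in temperature or handling between the plants also stay open, as untested.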

How the results depend on the processing

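All these alternatives were fixed before the data were examined. The SDG4 (AT4G30860) log2 ratio stayed between 1.59 and 2.196 in every setting run, with no adjusted p under 0.108. The number of genes past the threshold was 0 in each direction in every setting with a test, except that separate channels with no replicate block called 2 lower genes, a fit with more residual degrees of freedom. The correction for probe GC content, scaling between arrays, no background subtraction, the stricter filter (which gave no value for the genes it removed), keeping outlier spots, the mean over probes and the trended robust variance kept the list calls, the directions of the mean ratios named and every count within 1.5 times. Among medians of single arrays near 0, no background subtraction turned that of ovule and young seed genes on the replicate 1 array (-0.0013) and that of SET domain genes on the replicate 2 array (-0.0023). What follows are calls and directions that changed, counts that moved by over 1.5 times and some of the moves of other medians, and the cause was not tested unless given. Median centring left the median of all genes at 0.48 and 0.42 on the 2 arrays, because it does not remove the trend of the ratio with intensity, so its values are to be read relative to that shift.

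Under median centring, 190 genes were at least 2-fold higher and 3 lower on both arrays, against 25 and 5 with loess, and the Pearson and Spearman correlations were 0.14 and 0.24. The pollen median turned to 0.13 while the camera direction stayed lower. By camera, which compares a list with the other genes, 1 list was called higher, the reference genes (0.66, limma adjusted p = 0.0452), and 4 lower, namely pollen tube signalling (2.77e-06), pollen cell wall (0.00171), pollen transport (-0.11, 9.90e-06) and sperm cell genes (7.21e-04), although most of their medians lay above 0. The medians of the called lists were 1.55 for jasmonate (adjusted p = 0.365) and 2.96 for heat shock (adjusted p = 0.0839), both no longer called. Direction also turned for the medians of pollen tube signalling (0.081), pollen cell wall (0.21), pollen cytoskeleton (0.37), pollen transcription factors (0.26), sperm cell (0.24), SET domain (0.41), senescence (0.55) and cell cycle genes (0.49), and for SKS12 (0.090), VGD1 (0.13), ACT11 (0.20), TIP1;3 (0.076), AGL30 (0.073), AGL18 (0.42) and DAN1 (0.48). On single arrays it turned the replicate 1 medians of pollen cytoskeleton (0.031), tapetum (0.053), SET domain (0.39) and cell cycle genes (0.38), and the replicate 2 medians of photosynthesis (0.42), jasmonate (0.27), salicylate (0.34), cold and abscisic acid (0.42) and flavonoid genes (0.40).

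With the software's processed signals and, identically, the deposited log ratios, 78 genes were at least 2-fold higher and 23 lower on both arrays and 195 opposite, the Pearson correlation was -0.083, and the photosynthesis median turned to -0.076 and GRP17 to 0.55. On single arrays the sperm cell medians were -0.69 and 0.81, the pollen transport medians -1.18 and 0.50 and the pollen transcription factor medians -0.82 and 0.70, and the median turned for ovule and young seed genes on the replicate 1 array (-0.088) and SET domain genes on the replicate 2 array (-0.0055). An offset of 16 gave 9 genes lower on both arrays and turned GRP17 to 0.0011. No filter gave a Spearman correlation of -0.0014 and turned the tapetum median to -0.024, and the heat shock median was 0.70 over 9 members, still called, because 2 dim members were added. On the replicate 2 array no filter turned the salicylate median to 0.087 and the cold and abscisic acid median to 0.062, and the tapetum median there was 0.052. With an estimated correlation in camera, 0 lists were called, with the same medians of 2.42 for heat shock and 0.99 for jasmonate (adjusted p = 0.95 for both) and -0.30 for pollen (p = 0.703).

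Leaving out 1 array, with no test, gave counts of genes at least 2-fold apart from 195 to 547 higher and from 128 to 473 lower, since 1 array need not match the other. The pollen median ranged from -1.02 to 0.52 and the jasmonate median from -0.23 to 2.39, and the heat shock median from 1.57 to 3.28.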

Other observations

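These groups and genes were chosen after the results were seen. Among the genes with the highest ratios on the replicate 1 array that the lists did not hold, RRTF1 (AT4G34410), a transcription factor, gave 4.48 there and -0.97 on the replicate 2 array. DDF1 (AT1G12610), of the CBF family, gave 4.45 and -1.67, the glutaredoxin GRX480 4.06 and -0.25, the calmodulin-like CML37 3.83 and -0.66, and ERF13 3.48 and -0.34. By the array's descriptions, 20 of 80 AP2 domain factors were at least 2-fold higher on the replicate 1 array against 0 on the replicate 2 array, with family medians of 0.17 and -0.22 and no call over both arrays (camera adjusted p = 0.680, in the lower direction). Of 68 pectinesterase or pectate lyase genes, 16 were at least 2-fold lower and 2 higher on the replicate 1 array. On the replicate 2 array 5 were at least 2-fold higher and 1 lower. The medians of this family were above 0 on both arrays, at 0.05 and 0.21. Among the 12 families looked at, none passed camera over both arrays (smallest adjusted p = 0.208).

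Further genes at least 2-fold higher on both arrays included the coactivator MBF1C, at 1.80 and 4.14, AT1G07400 (HSP17.8-CI) at 2.28 and 4.09, AT2G20560, a DNAJ protein, at 2.06 and 3.40, BAG6, at 1.03 and 2.30, and AT5G48570, described as a peptidyl-prolyl isomerase, at 1.05 and 3.08, all higher on the replicate 2 array. AT1G53540 (HSP17.6C-CI) ran the other way, with 2.56 and 1.31. Of 149 genes described as heat shock or DNAJ proteins, 10 were at least 2-fold higher on both arrays, and the family medians were -0.01 and 0.03. HSFA7A gave -1.03 on the replicate 1 array and 3.02 on the replicate 2 array.

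SDG4 and HHP2 formed the 1 pair of adjacent tested genes, among 20154 such pairs, in which both were at least 2-fold higher on both arrays, where independent placing gives 0.0307. AT4G30830, 4 annotated genes from SDG4 on the side of HHP2, gave 1.49 and 0.95, while AT4G30840, which lies between AT4G30830 and HHP2, gave 0.01 and 0.40.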
